A study of Capra hircus with 6 samples.

How the data were processed

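ATAC-seq libraries were made from 50,000 mammary epithelial cells each with the Nextera Tn5 transposase and sequenced on a BGISEQ-500 instrument, per the labels' protocols. The labels put 3 libraries in the dry period group (replicates 1, 2 and 3) and 3 in the lactation group (replicates 1, 2 and 5). The submitters' processing notes name Bowtie2 2.2.5 and MACS2, with no role for either. The genome build, the program that called the differential regions, its windows and thresholds, any shift of reads for the Tn5 cut and any removal of duplicates or mitochondrial reads are not given in the sources used here. RNA-seq libraries were not analysed here.

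The data used are 1 table in which the authors deposited 30714 regions with their position, width, signal value, fold change, p-value, Benjamini-Hochberg FDR and name. The width column, named length per the file headers, holds another unit than the rest: bp, equal to end minus start in all 30714 rows, from 200 to 3000 bp in steps of 100. The deposited signal value is a score that equals the fold change times 1 constant per set (32.0 in set 1 and 20.4 in set 2, with a highest value of 1000), so it adds nothing to the fold and was not used. The deposited fold change is a linear ratio of one group over the other and lies above 1 in both sets, with a highest value of 31.2 in set 1 and 48.9 in set 2. The p-values and the FDR (a q-value) are those the authors deposited; every listed p lies under 0.001, and the FDR divided by p implies 13155099 tests in each set. The highest listed FDR was 0.270 in set 1 and 0.858 in set 2, so listing alone does not mean that a region passed an FDR of 0.05.

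The table holds no value per library, only values of the whole comparison. Tests across libraries, a correction for depth, a replicate block and leaving out single libraries were therefore not run, and the depth of each library is unknown. The count of differing regions was taken from the authors' FDR at 0.05, as set for this case before the data were examined. Which of the 2 sets is the dry period and which is lactation is not stated in the table or the labels. The planned share of regions more accessible in lactation was therefore replaced by the share in set 1. Numbers in the region names run without a gap to 22884 in set 1 and 7830 in set 2.

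Gene names came from a RefSeq gene table of the assembly ARS1.2. It was used for names, for which genes lie near a region, and for gene lengths, local gene numbers and tRNA genes. None of its coordinates are printed. The regions lie on 102 sequences, of which 29 are the numbered chromosomes, with 29978 regions. Because the build of the regions is not stated, the match was checked. On 29 of 29 chromosomes the regions lay within 1000 bp of gene ends more often for their own chromosome's genes than for those of any other. With each chromosome cut at its middle, that share was higher at the deposited position than 100000 bp away in 58 of 58 pieces. Coordinates of regions are the authors', counted from 1. The gene table gives no strand, so both ends of a gene stand in for its transcription start, which the plan had named; exons and introns were not separated. No genome sequence was used here, so the planned motif search and GC content were not analysed here, and only width and fold change were compared between the sets.

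A region was near a gene when its centre was within 3000 bp of an end of 1 of 19059 protein-coding genes on numbered chromosomes. The shares of the 2 sets near gene ends were compared with Fisher's exact test, 2-sided. For 16 gene lists with 443 entries, fixed before the data were examined, 409 of which matched a gene, each gene took the FDR under 0.05 region nearest to one of its ends within 50000 bp. The lists cover milk proteins, milk fat, lactose and sugar supply, amino acid and calcium transport, hormone signalling, involution, the cell cycle, luminal, basal, fibroblast, endothelial, adipocyte, immune, neural and housekeeping genes, and neighbours of loci used for transgene insertion. The split of each list between the sets was tested against all other genes with a region by Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over the lists. Genes that share a region are not independent, and neither are regions. A count adjusted over the list alone could not be made, because genes without a listed region have no p. The split per chromosome was tested in the same way, with adjustment over 29 chromosomes. Medians were compared with permutation tests of 100000 resamples. Intervals of shares are 95% Wilson intervals and cover counting error only.

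The rule for named genes was fixed before the data were examined. It takes up to 4 genes per list with the largest fold change of their nearest region, the 10 genes per set with the smallest authors' p among genes with a symbol and a region within 3000 bp of an end, the 3 regions per set with the smallest p, and every region at the casein cluster. Other list members named in the text are those in the smaller set of their list, or *ACACA*, *FASN* and *DRG1*, chosen after their values were seen. Some genes and regions that the rule takes are not reported here.

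The steps were tested on simulated data first. Distances equalled those of a direct search in 500 of 500 cases. Over 9620 genes with set names drawn at random, the list test found 43 of 80 lists (53.75%) with odds of set 2 raised 8 times and called 0 of 240 unchanged lists. Over 8330 regions, the chromosome test found 33 of 40 chromosomes (82.5%) with odds doubled and called 1 of 540 unchanged ones. Alternatives covered the FDR threshold, a minimum fold, placed chromosomes only, merging of regions within 100 bp, the distance to gene ends, and which region stands for a gene; others were added after seeing the data. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.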

Results

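Accessible chromatin was measured with ATAC-seq, in which the Tn5 transposase cuts and tags DNA that is not covered by nucleosomes, in mammary epithelial cells of the dairy goat. There were 3 libraries from the dry period, when the gland makes no milk, and 3 from lactation. From the series' title, the comparison of the 2 periods bears on where accessible chromatin lies in the lactating gland, as sites for placing transgenes. The deposited measurement is a table of 30714 regions from the comparison of the dry and the lactation libraries, each listed at a p under 0.001, whether or not it passed an FDR of 0.05, and each with the authors' fold change, p-value and false discovery rate (FDR). The regions carry names in 2 sets, called set 1 (22884 regions) and set 2 (7830 regions) here. Each set was taken to hold the regions more accessible in 1 of the 2 periods, since every fold change in both sets is above 1. Neither the table nor the labels state which set belongs to which period. The title of the table lists the dry period libraries first, so that set 1 would hold the regions more accessible in the dry period if the numbering follows that order. This was not settled, and every direction below is given by set. Read depth per library is unknown, and no value per library was used here. The labels do not say whether the libraries of a period came from separate goats, and how the authors' p-values treat the libraries is not given in the sources used here. At most those p-values measure the spread between these libraries, which may be technical.

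Differing regions were far more numerous in set 1 than in set 2. At an FDR under 0.05 there were 8543 regions, of which 7820 were in set 1 and 723 in set 2, a set 1 share of 91.5% (95% Wilson interval 90.9% to 92.1%, which covers counting error only). The authors' deposited table gave the lowest p of set 2 to a region on chromosome 9 at 91110801 to 91111300, more than 50000 bp from the nearest gene, with a fold change of 7.20 (p = 4.08e-28, FDR = 5.37e-21). Next in set 2 in the authors' deposited table was a region on chromosome 19 at 41750301 to 41751300, inside *TTC25*, a gene for a protein of motile cilia, with a fold change of 3.71 (FDR = 7.83e-21). This region is also the nearest to *ACLY*, the enzyme that makes cytosolic acetyl-CoA for fatty acid synthesis. A set 2 region inside *PLXNA2*, a semaphorin receptor, on chromosome 16 at 73781501 to 73782500 had a fold change of 6.48 in the authors' deposited table (FDR = 7.34e-19). Inside *TEX14*, a gene for germ cell bridges, a set 1 region on chromosome 19 at 9230901 to 9231900 had a fold change of 4.68 in the authors' deposited table (FDR = 1.32e-25).

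Set 2 regions were fewer, but their fold changes were larger. The median fold change in the authors' deposited table was 2.32 in set 1 (interquartile range 1.88 to 3.05) and 3.53 in set 2 (2.74 to 4.73), a difference of 1.21 (2-sided permutation test of the medians, p = 1e-05, the smallest that 100000 resamples can give). The median width was 400 bp in set 1 (300 to 500) and 500 bp in set 2 (400 to 600), a difference of 100 bp (2-sided permutation test, p = 2e-05). Regions are not independent replicates of animals, so these tests compare regions of 1 table. The p limit behind an FDR of 0.05 differed between the sets. The authors' p was 6.03e-05 for the *AGPAT1* region of set 1 (FDR = 0.0491) and 4.46e-06 for the *TEK* region of set 2 (FDR = 0.0428). Set 1 regions with an FDR under 0.01, a p limit closer to that of set 2, had a median width of 500 bp (400 to 600) and fold change of 2.33. At this closer p limit only the fold change thus stayed larger in set 2. Among regions picked by p, those with fewer reads need a larger fold to be listed. Read depth per region is unknown, so whether this gave the larger folds of set 2 was not tested. The set 1 share moved with the threshold: it was 75.2% of 1092 regions with a log2 fold change of at least 2, and 82.75% of 5229 regions at an unadjusted p under 1e-05 in both sets.

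Among regions with their centre within 3000 bp of an end of a named gene, set 1 was led by *QRSL1*, a subunit of the mitochondrial enzyme that forms glutaminyl-tRNA, and *ADAMTS4*, a protease that cleaves aggrecan in the extracellular matrix. The *QRSL1* region (chromosome 9, 30577801 to 30579000) had a fold change of 15.2 in the authors' deposited table (FDR = 3.21e-27). For the *ADAMTS4* region (chromosome 3, 111811501 to 111812700) the authors' deposited table gave 2.47 (FDR = 2.23e-20). *EYA3*, a phosphatase and transcriptional coactivator, followed with a set 1 region on chromosome 2 at 10677001 to 10677800, at a fold change of 5.53 by the authors' deposited table (FDR = 5.86e-10). Other set 1 genes named by the same rule were *TPGS1* (fold change of 2.58 in the authors' deposited table), *PSTPIP2* (3.00), *NBEAL2* (2.06) and *CAMSAP2*, which binds microtubule minus ends (2.13). *DUSP3*, a phosphatase, and *C19H17orf105* share 1 region, with a fold change of 1.72 in the authors' deposited table.

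Set 2 was led near gene ends by *PEF1*, a calcium-binding protein, *KIF14*, a kinesin of cell division, and *KCNH1*, a voltage-gated potassium channel. In the authors' deposited table the *PEF1* region (chromosome 2, 13878401 to 13879200) had a fold change of 3.92 (FDR = 5.96e-14). The *KIF14* region (chromosome 16, 77795101 to 77796300) had 6.89 in the authors' deposited table (FDR = 6.35e-14), and the *KCNH1* region (chromosome 16, 71264501 to 71265900) had 5.44 (FDR = 3.19e-13). *MPC1*, a subunit of the mitochondrial pyruvate carrier, had a smaller set 2 fold change of 1.54 in the authors' deposited table (FDR = 3.32e-08). A set 2 region inside *SPI1*, the gene for the myeloid and B cell transcription factor PU.1, on chromosome 15 at 5786401 to 5787200 had a fold change of 4.47 in the authors' deposited table (FDR = 0.000173). It also lies within 3000 bp of an end of *MYBPC3*, a gene for a heart muscle protein. The remaining set 2 genes of the rule were *IGSF5* (fold change of 3.50 in the authors' deposited table), *ST6GAL2*, a sialyltransferase (3.54), *SAFB2* (2.73) and *PIK3R3*, a regulatory subunit of phosphoinositide 3-kinase (2.05).

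The 2 sets lay in different places relative to genes. Of 7622 set 1 regions on chromosomes 1 to 29, 2625 (34.4%, 95% Wilson interval 33.4% to 35.5%) had their centre within 3000 bp of an end of a protein-coding gene, against 75 of 708 set 2 regions (10.6%, 8.54% to 13.1%). The odds ratio was 4.43 (Fisher's exact test, 2-sided, p = 2.47e-45), and the set 1 share was the higher on 29 of 29 chromosomes. Set 2 regions lay more often inside genes away from their ends, at 47.5% (43.8% to 51.1%) against 30.2% of set 1 regions (29.1% to 31.2%), and more often over 50000 bp from any gene, at 21.6% (18.7% to 24.8%) against 10.0% (9.38% to 10.7%). The rest, 25.4% of set 1 and 20.3% of set 2, lay outside genes within 50000 bp of a gene end. The median distance to a gene end was 7686 bp in set 1 and 32081 bp in set 2. Within set 1, the density was highest 500 to 750 bp from a gene end, with 361 regions against 273 at 0 to 250 bp. In set 2 it was highest at 0 to 250 bp, but with 16 regions there the counts are too few to place a peak. Over all 7664 listed set 2 regions on these chromosomes, whatever their FDR, the counts fell from 184 at 0 to 250 bp to 122 at 250 to 500 bp and 90 at 500 to 750 bp. Over the 22314 listed set 1 regions the counts in the same bins were 848, 1028 and 1100. The gene table used here gives no strand, so starts and ends of genes could not be told apart.

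**Figure D1:**
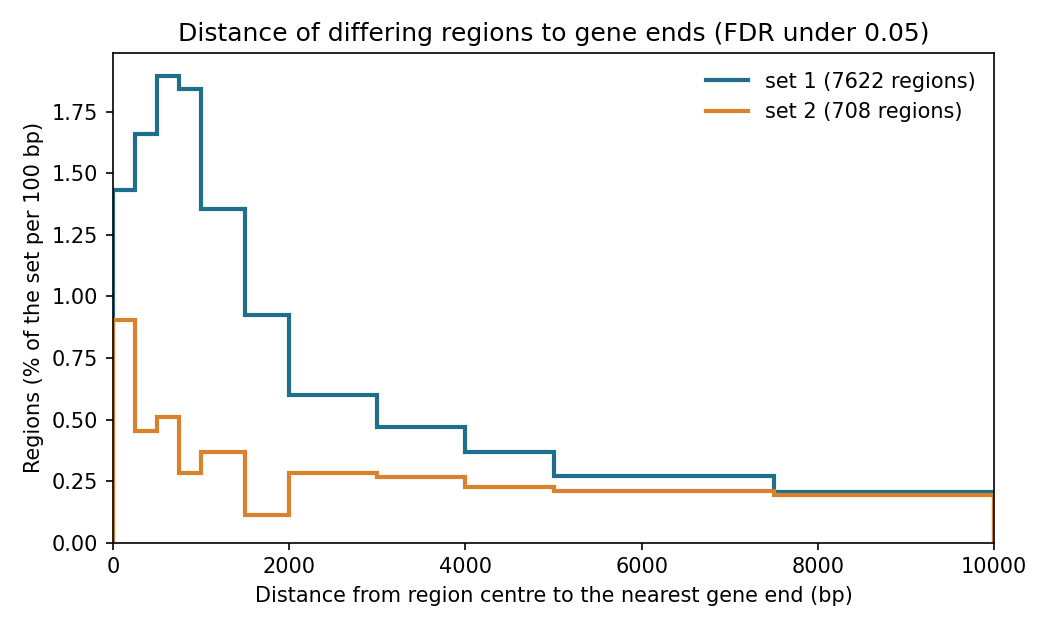
Density of differing regions by the distance of their centre to the nearest end of a protein-coding gene (x axis, bp; y axis, percent of the set's regions per 100 bp), for 7622 set 1 regions and 708 set 2 regions with an FDR under 0.05. The set 1 line peaks at 500 to 750 bp, at 1.89% per 100 bp, and the set 2 line is highest at 0 to 250 bp, at 0.904% per 100 bp from 16 regions.

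Genes of milk synthesis had their nearest differing region mostly in set 1, as did 9011 of all 9620 genes with a region. Of 28 milk fat genes with a region within 50000 bp of a gene end, 26 were in set 1 and 2, *ACLY* and the fatty acid elongase *ELOVL5*, in set 2. In the authors' deposited table the set 1 fold change was 5.99 for the region of *ACACB* and 2.39 for that of *ACACA*, both acetyl-CoA carboxylases. It was 4.24 for the acetyl-CoA synthetase *ACSS2*, 3.56 for the phosphatidate phosphatase *LPIN1* and 2.01 for the fatty acid synthase *FASN* in the authors' deposited table. The FDR of these regions lay near the limit for *ACACB* (0.0465), *LPIN1* (0.0462) and *ACSS2* (0.0396). It was 0.0310 for *FASN* and 3.9e-05 for *ACACA*. All 6 milk protein genes with a region were in set 1, among them the peroxidase *LPO* (fold change of 3.03 in the authors' deposited table), *PAEP*, which encodes beta-lactoglobulin (2.65), the immunoglobulin receptor *PIGR* (2.01) and *BTN1A1*, a protein of the milk fat globule membrane (2.08). The regions of *ACACA* and *LPIN1* lie inside the gene and within 3000 bp of an end of it, respectively, and those of *ACACB*, *ACSS2* and *FASN* outside the genes and farther than 3000 bp. The regions of *LPO*, *PAEP* and *PIGR* also lie outside the genes, 33743, 45069 and 34890 bp from an end. That of *BTN1A1* lies 1887 bp from an end, and only 1 milk protein gene had a region within 3000 bp. With every listed region, 3 of 12 milk protein genes were in set 2, against 20.5% of the other genes with a listed region. The *BTN1A1* region lies in a 1 Mb stretch of chromosome 23 that holds 108 set 1 regions and 0 set 2 regions, among 116 tRNA genes. For lactose synthesis and sugar supply the split was 7 genes against 1. *PFKFB3*, a regulator of glycolysis, was in set 2 at a fold change of 5.67 in the authors' deposited table. *B4GALT1*, the galactosyltransferase of lactose synthase (3.51 in the authors' deposited table, FDR = 0.0458), and the hexokinase *HK1* (2.76, FDR = 0.000221) were in set 1. Amino acid and calcium transport split 10 to 1. Its set 2 gene was the secretory pathway calcium pump *ATP2C2* (fold change of 4.18 in the authors' deposited table, FDR = 7.31e-11). *ATP2B2*, the calcium pump of the apical membrane (3.85 in the authors' deposited table), the zinc transporter *SLC30A2* (3.54) and the amino acid transporter chain *SLC3A2* (3.52) were in set 1.

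None of these 4 lists was shown to split differently from the other genes with a region. Over all 9620 genes, 609 (6.33%) were in set 2, so even a list wholly in set 1 could not pass. Fisher's exact test, 2-sided, gave p = 0.697 for milk fat (adjusted p = 0.929), 1 for milk proteins (adjusted p = 1), 0.407 for lactose (adjusted p = 0.724) and 0.513 for transport (adjusted p = 0.821), with Benjamini-Hochberg adjustment over 16 lists.

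At the casein genes *CSN1S1*, *CSN2*, *CSN1S2* and *CSN3*, which encode most of the protein of goat milk, no differing region was listed. The cluster on chromosome 6 with 100000 bp either side, 432.9 kb in all, held 0 regions at an FDR under 0.05 and 0 of any of the 30714 listed regions. By the authors' deposited table the nearest listed region lay 137.6 kb away on chromosome 6 at 85840701 to 85840900, in set 1, with a fold change of 1.95 and an FDR of 0.232. A table of differing regions does not show whether the cluster was open in both periods or closed in both.

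Hormone, involution and cell cycle genes were also found mostly in set 1. In prolactin, growth hormone and steroid signalling, 22 of 23 genes with a region were in set 1. The highest set 1 fold changes in the authors' deposited table were 8.25 for *PGR*, the progesterone receptor, from a region outside the gene and farther than 3000 bp from it, 4.92 inside *IRS1*, an adaptor of the insulin receptor, and 3.96 for *STAT5B*, which carries the prolactin signal. By the nearest region the exception was *PRLR*, the prolactin receptor itself, with a set 2 region inside the gene on chromosome 20 at 39079201 to 39079700 and a fold change of 6.43 in the authors' deposited table (p = 2.9e-06, FDR = 0.0324). With the region of the largest fold change in place of the nearest, 3 of the 23 genes were in set 2, against 7.73% of other genes. By the nearest region, all 33 involution and cell death genes with a region were in set 1, led in the authors' deposited table by *TGFBR2*, a receptor for transforming growth factor beta (10.2). By the authors' deposited table *FOXO1* (4.39), the interleukin 6 receptor chain *IL6ST* (4.21) and *STAT3* followed. *STAT3*, a driver of involution in mice, shares its region with *STAT5B*. Regions of *FOXO1*, *IL6ST* and *STAT3* lie outside the genes, 4137, 14437 and 34265 bp from an end, and that of *TGFBR2* within 3000 bp. All 19 cell cycle genes were in set 1, with *PCNA*, the sliding clamp of DNA replication, at a fold change of 6.30 in the authors' deposited table, *MKI67*, a proliferation marker, at 4.35, *PLK1* at 3.29 and *E2F1* at 2.94. The *PLK1* region lies outside the gene, 43743 bp from an end, and those of *PCNA*, *MKI67* and *E2F1* within 3000 bp. Other settings put some of these genes in set 2: 1 of 33 involution genes with the region of the largest fold change, 8 of 42 with every listed region, and 1 of 9 cell cycle genes at an FDR under 0.01. The exact p for the split against other genes was 1 for hormone signalling (adjusted p = 1), 0.268 for involution (adjusted p = 0.638) and 0.629 for the cell cycle (adjusted p = 0.915). The last 2 come from lists wholly in set 1, so no surplus of set 1 could have passed there.

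By the nearest region, no luminal or basal marker was in set 2, while the lists of other cell types each had 2 or 3 genes there; no list passed the test, and lists were not tested against each other. All 22 luminal marker genes with a region were in set 1, with *PGR* (8.25), *KRT18* (4.48), *GATA3* (4.33) and *FOXA1* (4.11) at the highest fold changes in the authors' deposited table. The last 2 are transcription factors of luminal cells. Their regions lie within 3000 bp of an end, and those of *PGR* and *KRT18* outside the genes, 28580 and 27441 bp away. All 14 basal and myoepithelial genes with a region were in set 1 too. Among them were the smooth muscle kinase *MYLK* (4.19 in the authors' deposited table, FDR = 0.0451), *ITGA6* (3.11, FDR = 0.0224) and *LIMA1* (2.72, FDR = 0.0282). With the region of the largest fold change, 1 of these 14 genes was in set 2, against 7.75% of other genes. With every listed region, 6 of 23 basal genes (26.1%) and 1 of 25 luminal genes were in set 2, against 5 of 18 endothelial genes (27.8%). In that setting 20.5% of the genes outside each of these lists were in set 2. Of 10 endothelial genes, 3 were in set 2. *VWF*, the von Willebrand factor, had a fold change of 8.76 in the authors' deposited table (FDR = 0.0184). The others were *TEK*, the angiopoietin receptor (2.99 in the authors' deposited table, FDR = 0.0428), and *CDH5*, the cadherin of endothelial junctions (2.40, FDR = 0.0421). *SOX18* (3.42, FDR = 0.0373) and *EGFL7* (2.94, FDR = 0.0106) were the highest of the 7 in set 1 by the authors' deposited table. Regions of *SOX18* and *EGFL7* lie outside the genes, 5050 and 3121 bp from an end, and those of *VWF*, *TEK* and *CDH5* inside. Immune markers split 12 to 3, with *SPI1*, the B cell antigen *MS4A1* (3.18 in the authors' deposited table, FDR = 0.000741) and *CSF3R* (2.48, FDR = 0.0299) in set 2. The chemokine receptor *CCR7* (3.54 in the authors' deposited table, FDR = 0.0427) and *CSF1R* (2.92, FDR = 0.0474) were highest in set 1. Regions of *MS4A1* and *CCR7* lie outside the genes, 8700 and 30704 bp from an end. Fibroblast markers split 6 to 2. The matrix genes *MFAP5* (4.48 in the authors' deposited table, FDR = 0.0276) and *SPARC* (2.24, FDR = 0.00379) were in set 2. Their regions lie outside the genes, 4494 and 13221 bp from an end. *FN1* (2.64 in the authors' deposited table) and *S100A4* (2.42), with regions within 3000 bp of an end, were in set 1. Adipocyte markers split 9 to 2, with *AQP7* (3.61 in the authors' deposited table, FDR = 0.0303) and *ADIPOQ*, which encodes adiponectin (1.87, FDR = 8.13e-07), in set 2. Their regions lie outside the genes, 46246 and 24945 bp from an end. By the authors' deposited table *GPD1* (4.27, FDR = 0.0435), *LIPE* (3.98, FDR = 0.0415) and *LEP* (3.83, FDR = 0.000981) were in set 1. These regions too lie outside the genes, 17658, 8210 and 8216 bp from an end.

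The neural list holds genes that mammary epithelium does not express, and 5 of them had a region. The glutamate receptors *GRIA2* (7.48 in the authors' deposited table) and *GRIA1* (2.50) were in set 2. *STMN2* (4.01 in the authors' deposited table), *DLG2* (2.31) and 1 further gene were in set 1. Housekeeping genes split 18 to 1, with *GUSB* (3.30), *RPS9* (3.21) and *RPL13A* (3.20) among the highest set 1 fold changes in the authors' deposited table. The set 2 gene of this list, *MRPS15*, shares its region with the immune marker *CSF3R*. Among neighbours of loci used for transgene insertion, *PRNP*, the prion protein gene, was in set 2 at a fold change of 7.29 in the authors' deposited table (FDR = 0.0246). *PAEP* (2.65), *EIF4ENIF1* (2.44), *SETD5* (2.06) and *DRG1* (1.65) were in set 1 by the authors' deposited table.

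No list passed Benjamini-Hochberg adjustment over the 16 lists in Fisher's exact test, and 2 had an unadjusted p under 0.05. The endothelial list had the lowest p (30.0% in set 2, exact p = 0.0217, adjusted p = 0.282), followed by the neural list (40.0% in set 2, exact p = 0.0352, adjusted p = 0.282). At an FDR under 0.01, 5 endothelial genes had a region and 0 of them were in set 2 (exact p = 1, adjusted p = 1). The exact p was 0.0650 for immune (adjusted p = 0.347), 0.0869 for fibroblast (adjusted p = 0.348) and 0.151 for adipocyte genes (adjusted p = 0.483). In the same exact test p was 0.396 for luminal (adjusted p = 0.724), 0.279 for transgene neighbours (adjusted p = 0.638), and 1 for basal and housekeeping genes (adjusted p = 1 for both). With few set 2 genes in all, the test had little power for small lists. On simulated data it found 43 of 80 lists whose odds of set 2 had been raised 8 times. That simulation covered only a surplus of set 2 and drew genes independently. A surplus of set 1 could not be found with these counts. Even for involution, the longest list, with 33 of 33 genes in set 1, the exact test gave p = 0.268.

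**Figure D2:**
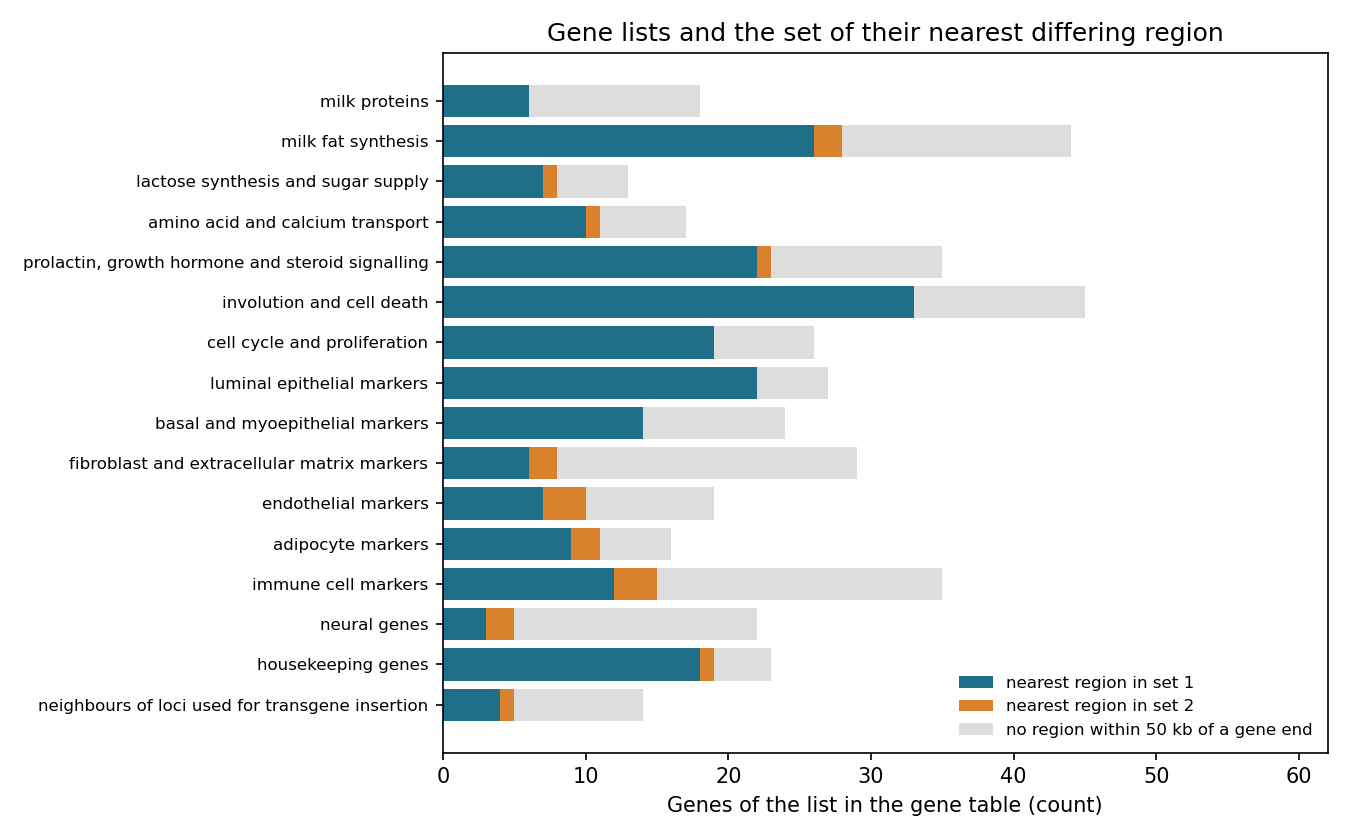
Genes of the 16 lists (x axis, number of genes in the gene table) by the set of their nearest differing region with an FDR under 0.05 within 50000 bp of a gene end; blue bars are set 1, orange bars set 2 and grey bars genes with no such region. Set 2 holds 3 of 10 endothelial genes with a region and 0 of 33 involution genes.

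Chromosomes 13 and 25 passed the test for a split between the sets that differs from the rest, but neither did so with distance to gene ends and local gene number held. On chromosome 13, the chromosome of *PRNP* and *PFKFB3*, 45 of the regions were in set 2 and 284 in set 1, a set 2 share of 13.7% against 8.29% on all other chromosomes (Fisher's exact test, 2-sided, p = 0.00118, adjusted p = 0.0171 over 29 chromosomes). Chromosome 25, which carries *GUSB* and *PLK1*, had 11 set 2 and 294 set 1 regions, a share of 3.61% against 8.69% (exact p = 0.000771, adjusted p = 0.0171). With set names permuted within classes of distance to gene ends and gene number, chromosome 25 had 0.908 times the set 2 regions that such permutations give (adjusted p = 0.964) and chromosome 13 had 1.43 times (adjusted p = 0.238). Neither passed with an FDR under 0.01 or with a log2 fold change of at least 1, where fewer regions entered and the shares stayed apart. Chromosome 13 had 14.5% against 8.76% (exact test, adjusted p = 0.118) and 17.6% against 11.1% (adjusted p = 0.0791) in these settings. Chromosome 25 had 2.72% against 9.23% (exact test, adjusted p = 0.0689) and 5.38% against 11.6% (adjusted p = 0.0956). With every listed region 16 chromosomes passed, chromosome 25 among them (13.6% in set 2 against 26.0%, exact test, adjusted p = 1.89e-19) and chromosome 13 not (27.7% against 25.5%, adjusted p = 0.134). A further 198 set 1 and 15 set 2 regions lay on sequences outside chromosomes 1 to 29.

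**Figure D3:**
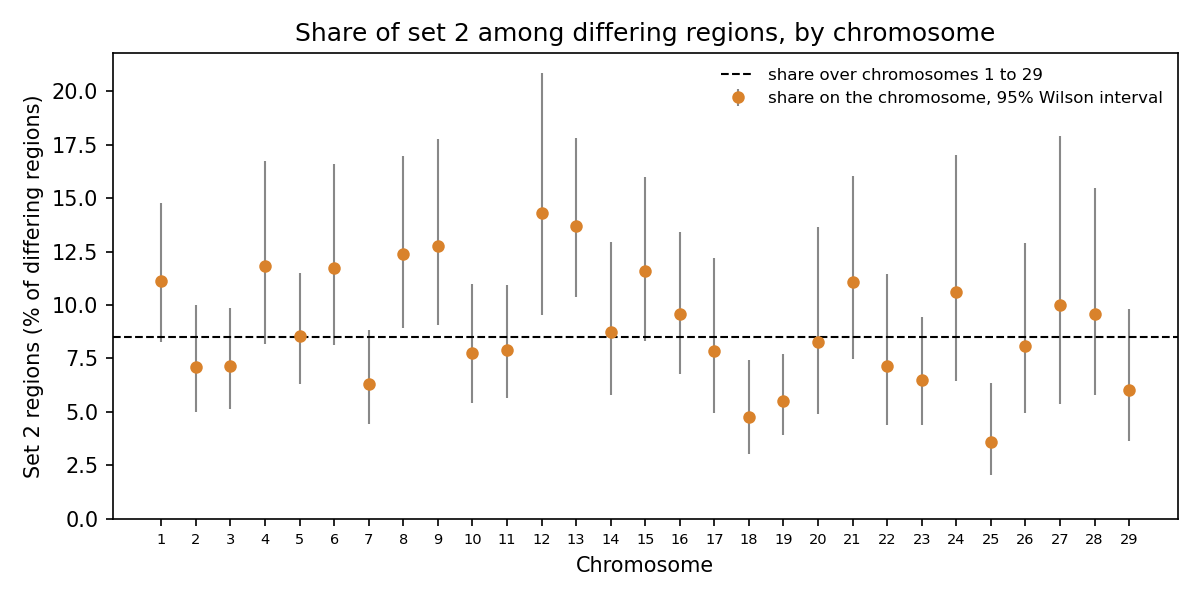
Share of set 2 among differing regions with an FDR under 0.05 (y axis, percent) on each of chromosomes 1 to 29 (x axis); points are shares, bars 95% Wilson intervals, and the dashed line is the share over all 29 chromosomes, 8.50%. Chromosome 13 lies at 13.7% and chromosome 25 at 3.61%.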

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

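The settings that use every listed region or an unadjusted p were chosen after seeing the data; the others were planned. At an FDR under 0.01 there were 4031 regions, with a log2 fold change of at least 2 there were 1092, with every listed region 30714, at an unadjusted p under 1e-05 in both sets 5229, and under 1e-10 302. The set 1 share was 88.7% with a log2 fold change of at least 1, 75.2% with at least 2, 74.5% with every listed region, 82.75% at a p under 1e-05 and 85.8% under 1e-10; set 1 stayed the larger set in each. The number of chromosomes past the threshold was 0 at an FDR under 0.01, 0 with a log2 fold change of at least 1 and 16 with every listed region. Fewer regions enter the first and second of these and more the last. The other 24 values of the main comparisons kept their side. Set 1 stayed nearer to gene ends by 11.7 to 23.3 percentage points, the casein cluster held 0 regions, and 0 lists passed in any setting. Set 2 kept the larger folds and widths with the same FDR limit in both sets. That limit is a smaller p in set 2: set 1 at an FDR under 0.01 and set 2 at an FDR under 0.05 both had a median width of 500 bp. In all 96 values of single lists the adjusted p stayed above 0.05, but the set 2 share of a list could lie above that of other genes in 1 setting and below in another, as for the endothelial list (30.0%, and 0% at an FDR under 0.01). The adjusted p of the endothelial list ranged from 0.282 to 1 and that of the neural list from 0.117 to 0.985. No paired analysis was possible because the table gives no value per library, although replicate numbers 1 and 2 occur in both groups. For the same reason TMM against DESeq2 or library size alone, filters on low counts or values, other pseudocounts, the block and leaving out single libraries were not run. Motif settings, matching on GC content and the authors' own annotation were not run either, for want of a genome sequence or such a column. Depth per library is unknown, so how far it limits the smaller set is open.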

Other observations

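Of the tests in this part, those on the surplus of set 1, on gene ends and on tRNA genes, and the choice of the chromosome 23 stretch and of the genes with the most regions, were made after the result was seen; those on gene lists, chromosomes and the casein cluster were not.

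Some genes held many differing regions, several of them long genes, and the counts were not adjusted for length. *TEAD1*, a transcription factor of the Hippo pathway, had 11 set 1 regions inside it or within 3000 bp of its ends (median fold change of 2.40 in the authors' deposited table), *PXN*, which encodes the focal adhesion protein paxillin, had 8 (1.77) and *KIAA1217* had 7 (3.04). *PXN* is 42.9 kb long, against 269.5 kb for *TEAD1* and 532.4 kb for *KIAA1217*, and lies in a 100 kb window of chromosome 17 (8500001 to 8600000) with 11 set 1 regions, shared with *GCN1*, *RPLP0* and *SIRT4*. In set 2, *SLCO3A1*, an organic anion transporter, had 7 regions (median fold change of 5.27 in the authors' deposited table), 4 of them in the 100 kb of chromosome 21 from 14200001 to 14300000, the densest such window of set 2. *ARHGAP25*, a regulator of Rac in blood cells, and *BCAS3* had 4 each. The lengths are 374.7 kb for *SLCO3A1*, 93.2 kb for *ARHGAP25* and 592.2 kb for *BCAS3*.

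Regions of set 1 gathered at tRNA genes. There were 101 of 7622 within 500 bp of 1 of 1574 tRNA genes (1.33%, exact 95% interval 1.08% to 1.61%), against at most 34 when all regions were moved by 5000 bp either way. So gene-rich surroundings on a scale wider than this move did not alone give this number. The same move also took regions away from protein-coding gene ends. The share within 3000 bp of one was 34.4% before and 22.2% to 22.4% after. Protein-coding gene ends close to tRNA genes can therefore not be set aside as a part of the number. In set 2 the count was 0 of 708 (exact 95% upper limit 0.520%). A stretch of 1 Mb of chromosome 23 from 18000001 to 19000000, which contains the 3 densest 100 kb windows of set 1, held 108 set 1 regions with a median fold change of 2.34 in the authors' deposited table, 0 set 2 regions, 116 tRNA genes and 34 protein-coding genes under 1000 bp without a symbol; 35 of the 101 regions lie there. Whether reads were shared between near-identical tRNA copies was not tested.

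The first pattern weighed is the surplus of set 1. Separate adjustment of p in the 2 sets could give a surplus at equal evidence, but at the same unadjusted p under 1e-05 there were still 4.80 set 1 regions per set 2 region, which argues against it as the whole cause. A difference in read depth, scaling or signal over background between the 2 groups of libraries stays open. There were 35 set 1 regions per set 2 region within 3000 bp of gene ends and 7.89 elsewhere, but the table holds no read depth per region, so a technical gain at strongly open sites cannot be told apart from a change between the dry period and lactation. That biological difference was not tested.

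The second pattern is that set 2 regions lie near gene ends less often than set 1 regions. Within 3000 bp of an end lay 34.4% of set 1 regions, against 17.1% to 18.3% when they were moved by 50000 or 100000 bp either way. For set 2 it was 10.6%, against 8.76% to 12.3%. So set 1 gathered near gene ends, while set 2 was not shown to avoid them. The moved set 2 regions also had the lower shares, so surroundings with fewer gene ends are part of the contrast. If set 2 were false calls at random positions, its share within 500 bp of gene ends would match that of shifted positions. Over all listed set 2 regions the share was 4.01% (95% Wilson interval 3.59% to 4.47%), against at most 1.93% at the 4 positions 50000 and 100000 bp away. That argues against random positions for every listed set 2 region, but not for a large part of them. The FDR of listed set 2 regions reaches 0.858, so many of them may be false calls. For the 708 regions with an FDR under 0.05 the share within 500 bp was 3.39% (2.29% to 4.99%) against at most 2.68%. For these the counts are too few to exclude random positions. The test bears on position only, since false calls that gather near gene ends would pass it too. A difference between the periods in distal elements may also underlie the pattern and was not tested.

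The third pattern concerns which gene lists have any set 1 region within 50000 bp of their genes, nearest or not. In a 2-sided test against 10000 random lists matched on gene length and local gene number, 6 of 16 lists lay outside for set 1 after Benjamini-Hochberg adjustment. Length and crowding alone thus did not give these counts. The random lists drew each gene independently, whereas some list genes share a region, as *CLDN3* and *CLDN4* do. The random lists may therefore vary too little, and the p-values may be too small. By this permutation test luminal markers (23 of 27 genes, matched median 13, adjusted p = 0.0032), involution (33 of 45, median 21, adjusted p = 0.0032), hormone signalling (23 of 35, median 16, adjusted p = 0.0368), the cell cycle (19 of 26, median 12, adjusted p = 0.0368) and housekeeping genes (18 of 23, median 12, adjusted p = 0.0368) lay above, and neural genes (3 of 22, median 9, adjusted p = 0.0368) below. Milk proteins did not lie outside, with 6 of 18 genes against a median of 9 (permutation test, adjusted p = 0.341), and for set 2, 0 of 16 lists lay outside, with counts too low to decide. Since housekeeping genes stood out with luminal ones, the set 1 pattern may follow genes open in these cells in general, by signal over background or by biology, and GC content was not analysed here.

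With set names permuted within classes of distance to gene ends and local gene number, 0 of the 2 chromosomes kept an adjusted p under 0.05: chromosome 25 went to 0.908 times the number of set 2 regions such permutations give (p = 0.766, adjusted p = 0.964). Chromosome 13, at 13.7% against 8.29% elsewhere before, still had 1.43 times that number (permutation p = 0.0082), and its call ended with adjustment over the 29 chromosomes (adjusted p = 0.238), so part of its excess stays open. Of random windows as long as the casein cluster and with a gene number within 2 of its 8, 3.07% held no listed region, and the median window held 8. That share is below the limit set before the result was seen. So an empty window was uncommon at this length and gene number, though not excluded. With any gene number, 26.4% held none, but these windows were not matched to the cluster.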
